A study of Nicotiana attenuata with 48 samples.

How the data were processed

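Total RNA from leaves and roots of grafted Nicotiana attenuata plants was labelled with Cy3 and hybridised to single-channel Agilent arrays, per the labels. There were 48 arrays in 12 groups of 4, made of 2 tissues, 3 graft genotypes and 2 watering regimes. Per the file headers, each scan was read with Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.5. Per the file headers and column names, each deposited scanner file gives 2 kinds of spot intensity: the processed intensity, which is background-subtracted and spatially detrended, and the raw median intensity of the spot and of its local background. No column of these files is normalised between arrays, per the file headers. The series matrix deposited with them holds the authors' own values on a log2 scale. How the authors made that table is not stated, so its scale was read from the values. Its columns had medians of 6.40 to 6.43 and near-identical quantiles, and each correlated at 0.992 or more with the log2 raw median intensity of its own array. The best match was the own array in all columns except that of leaf ET control replicate 2. These values were therefore not centred per gene, and the remaining steps behind them stay unknown.

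The array carries 57157 probes on 61657 non-control spots, and 500 of the probes have 10 spots each. Of the probes, 48408 bear names of NIATv7 gene models, 3656 of NIATv1 models, 2810 carry PRID names and 2283 carry XLOC names. The NIATv7 probes belong to 31796 gene models, of which 10157 have 2 or more probes. None of these identifiers matched the reference table of 39977 genes (0 matches), and the files pair no probe with a gene name. Genes are therefore given by the identifier of the array, without location or function.

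Main values were log2 of the processed intensity minus the 75th percentile of all non-control spots of the array. Spots marked as outliers by the scanner software were left out, and the spots of a probe were averaged. A probe was tested in a tissue when it was well above background on at least 3 of the 4 arrays of at least 1 group of that tissue, which left 30772 probes in leaves and 33013 in roots. For a group in which a probe was well above background on 0 arrays, the brighter group was compared with the higher of the lowest well-above-background signal and the dim probe's own signal of each array, and the ratio is given as "at least".

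Each tissue was fitted apart with limma 3.58.1 in R 4.3.3, with a mean for each of its 6 groups over 24 arrays, moderated variances and 2-sided tests. The 9 contrasts per tissue were the drought response in each genotype, the genotype differences averaged over both regimes, and the differences between drought responses (interactions). P-values were adjusted with the Benjamini-Hochberg method over the probes of a contrast, and a probe was called at an adjusted p under 0.05. Changes are given as log2 differences ± standard error of the fit, with 4 arrays in each group, and group values as mean ± SD. Nothing in the labels says whether replicates came from separate plants, so the p-values measure only the spread between these samples. The number of arrays limits the precision. On simulated data with known changes among 30772 probes, the leaf drought contrast in EE recovered 28.4% of 1.5-fold, 71.6% of 2-fold and 92.4% of 4-fold changes. The root interaction of TT and EE, among 33013 probes, recovered 2.99%, 44.8% and 80.3% of them. Only 66 or 67 probes were changed at each fold. The adjusted threshold was thus stricter than in reported contrasts with many more calls. These rates therefore do not describe the reported drought contrasts, where most tested probes were called.

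Because probes carry no names, at most 2 risen and 2 fallen identifiers are named per contrast. They are those with the largest change among probes called with a fold of 2 or more that were well above background on at least 3 of 4 arrays of every group compared, with 1 probe per gene, the brightest on average. In drought contrasts the values of the 4 drought and the 4 control arrays of a named probe did not overlap. A few further genes were chosen after their values were seen, as said where they appear. The tests, contrasts, thresholds, naming rule and the alternative settings, except those named as added, were chosen before the data were examined. The planned naming rule held no condition on signal above background. That condition leaves out genes that are bright in only some of the groups compared. The line marker rule, the tissue-biased probe sets and the response sizes were made after the data were examined.

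Within a tissue, replicates 1 and 2 of a genotype share a slide with no other genotype of that tissue, and replicates 3 and 4 lie on slides that mix genotypes. Slide explained 44.1% of the residual variation in leaves and 47.3% in roots, against 27.8% by chance, and scan day 23.7% and 24.0% against 11.1%. Replicate number explained 20.6% and 33.2% against 16.7%, and the presence of a fitted spike-in curve, which arrays of replicates 1 and 2 have and those of 3 and 4 lack (slope 0), 9.37% and 15.8% against 5.56%. Genotype contrasts are therefore given also with slide as a fixed block and within each pair of replicates. Further alternatives were normexp background correction of the raw median intensity with an offset of 50 (the files hold no mean intensity, on which it was planned), quantile normalisation, no filter on dim probes, a stricter filter, slide as a random block, the replicate number as a block, an intensity trend with robust variances, only the groups of a contrast, the authors' log2 values, and each array left out in turn. Those added after the values were seen are named in the closing part on processing.

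Response size was the slope, without an intercept, of a genotype's drought changes across probes on the mean drought changes of all 3 genotypes. Probes with large changes therefore weigh most. The reference was taken from the other pair of replicates so that no array served on both sides. Differences in size were tested by exact permutation over 1296 relabellings. On simulated data with a true ratio of 0.8 the response sizes gave a ratio of 0.798 for 30772 leaf probes and 0.801 for 33013 root probes. Correlations across probes describe agreement only, since probes are not independent replicates. Where contrasts share arrays, 20 simulations without effects gave the value that sharing alone produces. Planned tests of 18 gene lists and of TOC1 probes were not run, because they need gene names. Tables were handled with python 3.11.15, pandas 2.3.3, numpy 2.4.6, data.table (1.17.8) and statmod 1.5.0, and figures drawn with matplotlib 3.10.9.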

Results

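Transcript levels were measured in leaves and roots of grafted Nicotiana attenuata, a wild tobacco, with 48 single-channel arrays. Plants carried a scion and a rootstock of either the empty-vector line EV or irTOC1, a line in which the clock gene TOC1 is silenced. EE plants joined EV to EV, ET plants had an EV scion on an irTOC1 rootstock, and TT plants joined irTOC1 to irTOC1. Water was withheld for 7 days from the age of 13 days, or normal watering went on, and tissues were taken at 20 days at around 7 pm. Each of the 12 groups of tissue, genotype and watering regime held 4 arrays. Leaf arrays had 26165 to 30879 of 57157 probes well above background and root arrays 29113 to 32071. The 75th percentile of processed signal lay between 197 and 592, and 0 probes were saturated. Arrays of the same group correlated across all probes at 0.952 to 0.994.

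The first question was whether the arrays carry the graft genotypes their labels state. No probe could be tied to TOC1, so the silenced transcript itself was not analysed here. Instead, 5 probes separated EE from TT arrays by at least 1 log2 unit in both tissues and both regimes, all lower in TT, by a rule made after the data were seen and without use of ET arrays. NIATv7_g03207 had the widest gap, with 8.17 ± 0.14 in EE and -2.96 ± 0.10 in TT control leaves (log2 normalised signal, mean ± SD, n = 4). That is a 2249-fold difference, and in control roots it was 594-fold. Under drought the level of NIATv7_g03207 in TT rose to 1.03 ± 0.26 in leaves and 1.67 ± 0.26 in roots, and the difference shrank to 114-fold and 72.5-fold. The other markers were NIATv7_g08159, NIATv7_g28929, NIATv7_g32196 and NIATv7_g15373.

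On an index of these markers, where the TT mean is 0 and the EE mean is 1, the 8 ET leaf arrays lay between 0.899 and 1.13. Of the 8 ET root arrays, 6 lay between -0.047 and 0.042. Root ET control replicate 3 read 0.947 and was closer to EE than to TT at 5 of 5 markers, and root ET drought replicate 2 read 0.213 and was closer to EE at 2 of 5. NIATv7_g28929 went another way, since ET roots held it at the EE level: -0.18 ± 0.74 in ET, -0.56 ± 0.85 in EE and -6.06 ± 1.0 in TT control roots. No TT control root array had it well above background, and EE roots were at least 15.5-fold and ET roots at least 20.1-fold higher than TT roots.

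**Figure D1:**
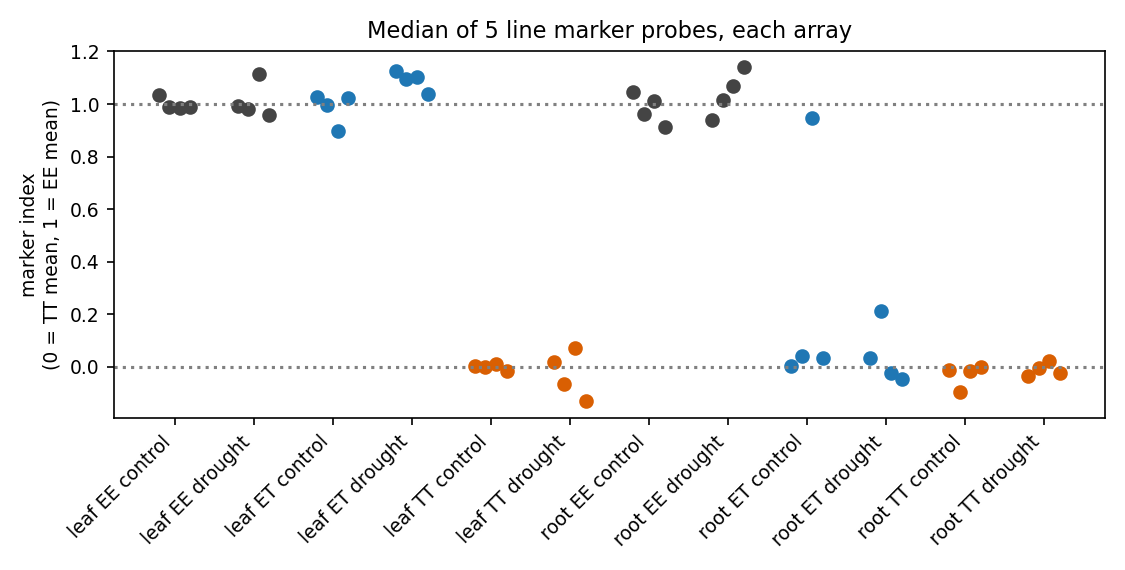
Line marker index of each array (vertical axis, no unit, TT mean 0 and EE mean 1) by group, with 1 point per array and dotted lines at 0 and 1. ET leaf arrays lie between 0.899 and 1.13, and root ET control replicate 3 lies at 0.947 while 6 of the ET root arrays lie between -0.047 and 0.042.

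Next came the question of what 7 days without water changed in leaves. In EE leaves 9793 probes rose and 10527 fell, which is 66.0% of the 30772 probes tested, and 9958 of them changed 2-fold or more. The balance of risen and fallen leaf probes depends on the scaling, with 7807 and 12462 in EE after normexp and 11600 and 9084 with scaling over detected probes. ET leaves had 10406 risen and 10741 fallen probes and TT leaves 10392 and 10481. All 3 genotypes shared 7710 risen and 8517 fallen probes, and only 169 probes were called in opposite directions in any pair of genotypes. NIATv7_g06269 was among the named risers of every genotype, with 8.09 ± 0.33 (adjusted p 3.7e-14), 8.65 and 8.73 on the log2 scale in EE, ET and TT. NIATv7_g14656 rose by 7.81 ± 0.43 in EE, and NIATv7_g01571 by 8.98 ± 0.49 in ET and 9.42 ± 0.49 in TT. Among probes above background in both regimes, the largest falls were those of PRID1968079611, at -9.14 ± 0.42 in EE, -8.76 in ET and -8.64 in TT, and of NIATv7_g19381, at -8.38 ± 0.41, -8.63 and -9.38. For each of these the 4 drought and the 4 control arrays did not overlap. Changes of replicates 1 and 2 correlated across probes with those of replicates 3 and 4 at 0.942 in EE, 0.930 in ET and 0.963 in TT.

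In roots the same question gave 9264 risen and 9197 fallen probes in EE, 55.9% of the 33013 tested. ET roots had 10729 and 10340, and TT roots 11019 and 10495. Probes with a change of 2-fold or more numbered 8121 in EE, 10420 in ET and 11110 in TT. The genotypes shared 7860 risen and 7822 fallen probes, and 84 were called in opposite directions. NIATv7_g14435 rose by 8.70 ± 0.85 in EE (adjusted p 3.3e-08), 9.31 in ET and 9.39 in TT. NIATv7_g20557 rose by 8.58 ± 0.49 in EE and 8.60 in TT, and NIATv7_g19677 by 8.23 ± 0.31 in ET. Among fallen probes, NIATv7_g29168 changed by -8.80 ± 0.32 in ET and -8.0 ± 0.32 in TT, NIATv7_g08453 by -7.77 ± 0.32 in ET and NIATv7_g19342 by -7.24 ± 0.43 in TT. In EE roots the largest falls among probes above background in both regimes were smaller, at -6.31 ± 0.40 for PRID1968082758 and -6.12 ± 0.68 for NIATv7_g30051. Here too the arrays of both regimes did not overlap, and the replicate pairs correlated at 0.935, 0.949 and 0.938. With only replicates 3 and 4, root calls numbered 11660 in EE, 13773 in ET and 13880 in TT.

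Leaf and root responses were compared over the 29125 probes tested in both tissues. In EE the log2 changes correlated across probes at 0.548, with 10065 probes called in the same direction and 1816 in opposite directions. Shared were 5136 risen and 4929 fallen probes, where independent lists would share 2755 and 2546. The correlation was 0.580 in ET and 0.615 in TT. A core of 4104 probes rose and 3942 fell in both tissues of all genotypes. NIATv7_g06269 rose in all 6 comparisons, by 8.09 to 8.73 in leaves and by 5.65 to 5.94 in roots, and NIATv7_g37553 by 5.52 to 5.58 and by 6.33 to 7.12. NIATv7_g01213 changed by -6.80 to -5.67 in leaves and -5.63 to -4.29 in roots, and NIATv7_g39687 by -5.81 to -5.46 and -4.84 to -3.96. Fewer probes went opposite ways in every genotype: 270 rose in leaves and fell in roots, among them XLOC_018744.t1.cds1 (2.19 in EE leaves, -1.68 in EE roots) and NIATv7_g21505 (2.11 and -1.52). Another 618 fell in leaves and rose in roots, such as NIATv7_g14323 (-3.25 and 3.0) and NIATv7_g32418 (-3.18 and 2.31). The largest adjusted p of these 8 genes in any of the 6 contrasts was 0.00025.

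**Figure D2:**
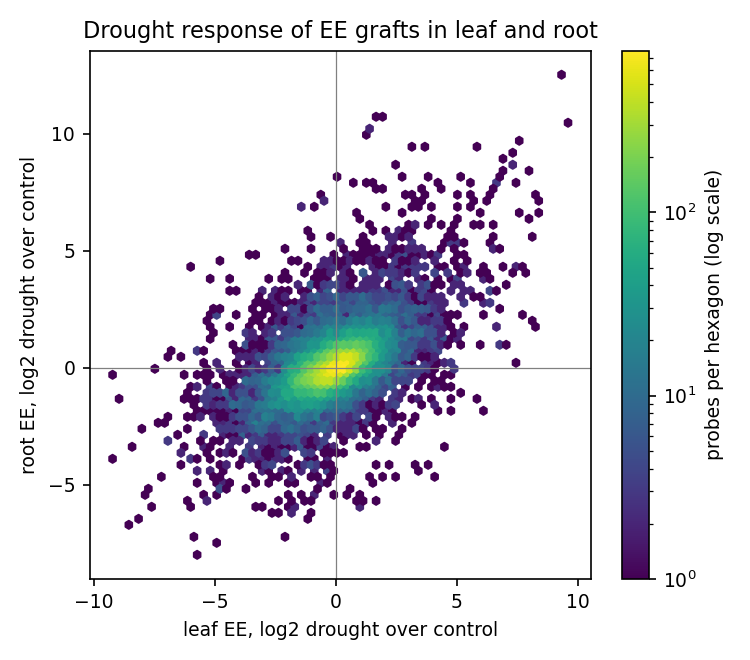
Drought response of EE grafts, log2 drought over control in leaves (horizontal axis) and roots (vertical axis), with hexagons shaded by their number of probes on a log scale. The correlation across 29125 probes is 0.548, with 10065 probes called in the same direction and 1816 in opposite directions.

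Tissue character under drought was followed with probes at least 3 log2 units brighter in 1 tissue in well-watered ET and TT plants. They were read in EE plants, whose arrays took no part in that comparison. However, the detection filter of both tissues used all groups, EE drought included. A probe dim in the control arrays of its darker tissue could thus enter through its drought signal, which favours a rise there. Of 2499 leaf-biased probes, 1650 fell and 290 rose in EE leaves, with a median change of -0.82. In EE roots 1155 of the same probes rose and 294 fell, with a median of 0.49. The medians of single EE drought root arrays ranged widely, from 0.053 to 0.735. Of 1291 root-biased probes, 639 fell and 305 rose in EE roots, with a median of -0.53. In EE leaves 613 of them rose and 345 fell, with a median of 0.59, but normexp background correction gave a median of -0.17, so no direction is stated for this set in leaves. Medians of all probes were -0.02 in leaves and 0.00014 in roots. Among probes above background in both regimes, 1625 of 2469 leaf-biased probes fell and 287 rose in leaves, and 895 of 2014 rose and 226 fell in roots. Signal above background was judged there on the EE arrays themselves, drought included. All of these counts have no test of the set against other probes, and the 3-unit threshold was set after the data were seen.

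Genotype differences averaged over both regimes ask what a silenced rootstock, alone or with a silenced scion, changes in leaves. ET and EE leaves, which share the scion, differed at 4598 probes, with 2296 higher and 2302 lower in ET, and 552 of these 2-fold or more. Leaving out 1 array gave 2753 to 6086 calls, with 2753 and 3056 without ET control replicates 1 and 2 and 2996 without ET drought replicate 1. NIATv7_g19342 was lower in ET (log2 difference -2.74 ± 0.16, adjusted p 7.4e-10) and NIATv7_g01536 likewise (-2.80 ± 0.48, adjusted p 0.0010). NIATv7_g33709 was higher by 1.66 ± 0.24 and NIATv7_g42554 by 1.60 ± 0.29. The difference of NIATv7_g01536 lay mainly under drought, with 3.30 ± 0.64 in EE and -1.22 ± 0.41 in ET. In control leaves it read -1.13 ± 1.82 and -2.21 ± 1.1. With slide as a block 623 probes were called, 556 of them among the 4598, and the median difference of the 4598 went from 0.47 to 0.35. NIATv7_g19342 stayed past the threshold (-2.49, adjusted p 2.2e-05) and NIATv7_g01536 did not (-2.24, adjusted p 0.124). Replicates 1 and 2, where each genotype's leaf arrays have a slide of their own, gave 8289 calls, and replicates 3 and 4 with slide as a block gave 238, with a correlation of 0.385 between these pairs.

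TT and EE leaves differed at 5362 probes, 2755 higher and 2607 lower in TT. Apart from the line marker NIATv7_g03207 (-8.98 ± 0.11, adjusted p 1.5e-23), NIATv7_g19752 was the most reduced of the probes eligible for naming, which were above background in every group compared, at -2.84 ± 0.22 (adjusted p 5.4e-09). NIATv7_g36183 was higher by 2.84 ± 0.11 (adjusted p 1.9e-13) and NIATv7_g03646 by 2.83 ± 0.11, although 1 of the 3 probes of NIATv7_g03646 went the other way. Slide as a block left 3348 calls, 2824 of them shared, and these genes all held. TT and ET leaves, which share the rootstock, differed at 7583 probes, 3883 higher and 3700 lower in TT. NIATv7_g01132 was higher by 3.11 ± 0.23 and NIATv7_g09022 by 2.98 ± 0.29, while NIATv7_g04799 was lower (-2.88 ± 0.18), as was NIATv7_g03207 (-8.58 ± 0.11). The difference of NIATv7_g09022 lay under drought, with -4.02 ± 0.91 in ET and 1.97 ± 0.42 in TT. In control leaves it read -0.34 ± 0.42 and -0.37 ± 0.74. With slide as a block 2159 probes were called, 1995 of them shared, and all of these genes held. The pairs of replicates correlated at 0.674 for TT and EE and 0.493 for TT and ET. Differences of ET and TT from EE correlated at 0.353 across probes, below the 0.498 that sharing the EE arrays alone gives, and at 0.0856 to 0.295 with those arrays split. Their covariance was 0.0540 against 0.0164 from sharing, and 1364 probes were called in both in the same direction and 227 in opposite directions.

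**Figure D3:**
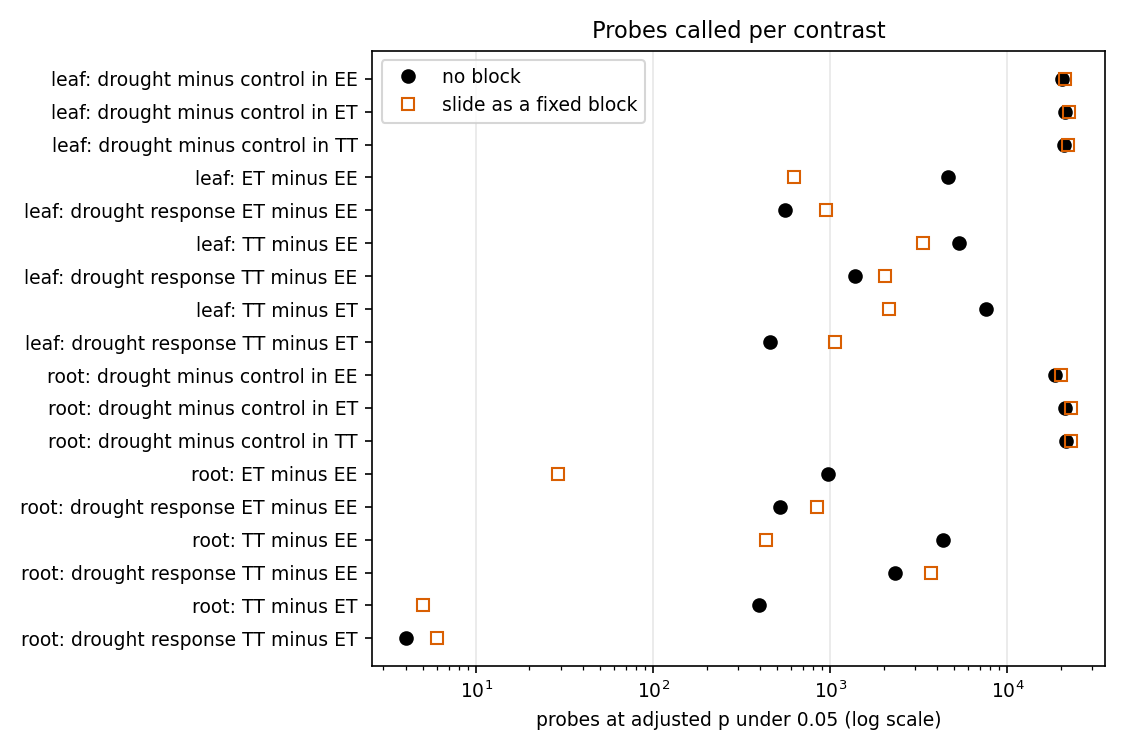
Number of probes at an adjusted p under 0.05 (horizontal axis, log scale) in each of 18 contrasts, without a block (filled circles) and with slide as a fixed block (open squares). Drought contrasts lie between 18461 and 21514 without the block, and root ET minus EE goes from 967 to 29.

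In roots the genotype contrasts ask what silencing of the rootstock changes and whether the scion adds to it. ET and EE roots differed at 967 probes (523 higher, 444 lower in ET) and TT and EE roots at 4319 (2117 and 2202). TT and ET roots, which share the silenced rootstock, differed at 398, with 61 higher and 337 lower in TT. Scaling over detected probes gave 417 higher and 573 lower probes for ET and EE. Leaving out 1 array gave 3190 to 5069 calls for TT and EE. For ET and EE it gave 523 to 1183, with 532 without EE control replicate 2, 523 without ET drought replicate 1 and 579 without ET control replicate 2. For TT and ET it gave 203 to 825, with 203 without TT drought replicate 1 or 2, 248 without TT control replicate 3, 258 and 249 without ET control replicates 1 and 2, 230 without ET drought replicate 3 and 825 without TT drought replicate 4. The marker NIATv7_g03207 was lower in ET by a log2 difference of -6.03 ± 0.91 (-7.53 without the 2 ET root arrays with unusual marker readings) and in TT by -7.70 ± 0.91. NIATv7_g34157 was lower in ET (-3.07 ± 0.52) and NIATv7_g22454 and NIATv7_g05912 higher (1.73 ± 0.22 and 1.51 ± 0.20). In TT, NIATv7_g07636 was lower than in EE (-3.43 ± 0.59), and PRID1968010931 and NIATv7_g06196 were higher (2.47 ± 0.50 and 2.38 ± 0.59). The last 2 differed mainly under drought, where EE roots were scattered. PRID1968010931 read -1.10 ± 2.12 in EE and 2.98 ± 0.73 in TT drought roots, against 3.17 and 4.03 in control roots. NIATv7_g06196 read -3.42 ± 2.49 and 0.39 ± 0.86 in drought roots, against 1.02 and 1.97 in control roots. NIATv7_g27226 and NIATv7_g09519 were lower in TT than in ET roots, by -1.41 ± 0.24 and -1.37 ± 0.16. Their adjusted p values lay between 3.7e-05 and 0.0116 in these fits.

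Most of these root calls did not hold with slide as a block, which left 29 for ET and EE, 432 for TT and EE and 5 for TT and ET. All of the unblocked calls kept their direction, and their median difference went from 0.66 to 0.62, from 0.51 to 0.44 and from 0.63 to 0.58, while the median standard error rose from 0.144 to 0.200, from 0.122 to 0.164 and from 0.125 to 0.171. The calls thus ended mainly through a wider error. Of the genes named, only NIATv7_g05912 (1.64, adjusted p 0.0249) and NIATv7_g03207 in TT (-7.74, adjusted p 0.0149) stayed past the threshold, while none changed direction. NIATv7_g03207 in ET kept its size (-5.96) with an adjusted p of 0.142. Replicates 3 and 4 with slide as a block gave 3, 47 and 0 calls in limma, with 1752 probes at an unadjusted p under 0.05 in the last of these fits. The replicate pairs correlated at 0.573, 0.561 and 0.234. Leaving out both ET root arrays with unusual marker readings gave 731 calls for ET and EE and 255 for TT and ET. Called in both contrasts against EE and in the same direction were 755 probes and 1 went opposite ways, in contrasts that share the EE arrays. Their log2 differences correlated at 0.746, against 0.503 from sharing the EE arrays alone and 0.254 to 0.571 with those arrays split.

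**Figure D4:**
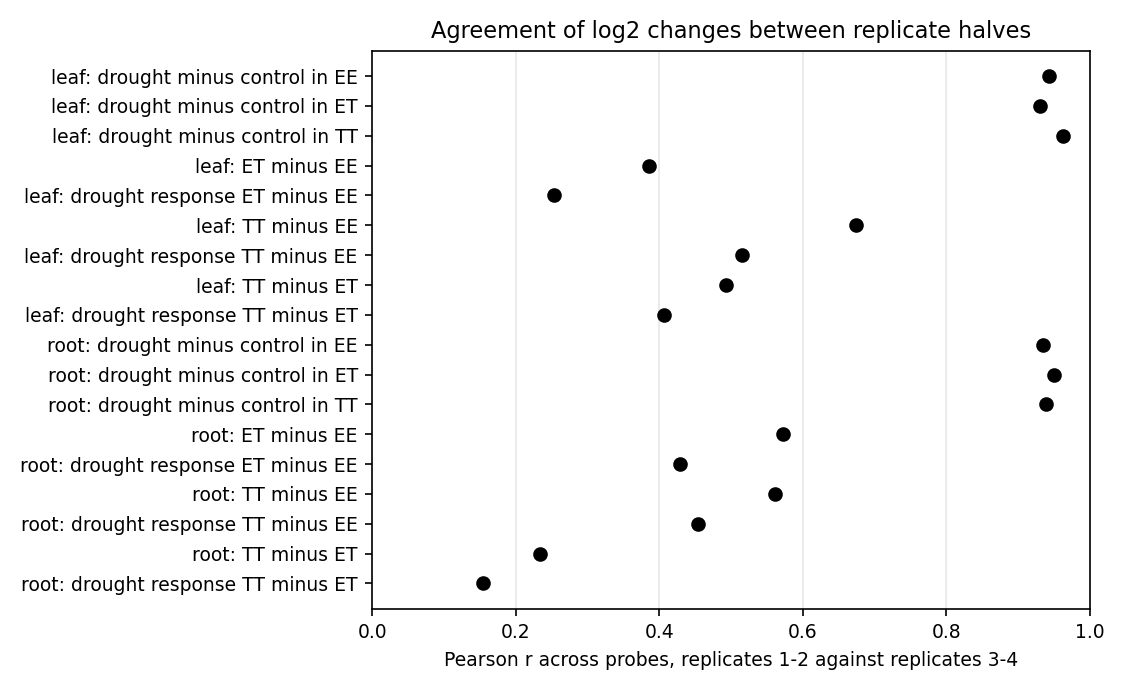
Pearson correlation across probes (horizontal axis, no unit) between log2 changes of replicates 1 and 2 and those of replicates 3 and 4, with 1 point for each of 18 contrasts. Drought contrasts lie between 0.930 and 0.963, and the root drought response of TT minus ET is lowest at 0.154.

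The series title puts at its centre whether root silencing changes the response to drought, which the interaction contrasts test. In leaves the response of ET differed from that of EE at 556 probes (225 up, 331 down), that of TT from EE at 1382 (793 and 589) and that of TT from ET at 454 (310 and 144). Leaving out 1 array gave 318 to 627 calls for ET and EE (338 without EE drought replicate 4, 318 without ET control replicate 3) and 916 to 1627 for TT and EE (916 without TT drought replicate 2). For TT and ET it gave 246 to 599, with 285 and 246 without TT drought replicates 1 and 2, 302 and 294 without ET control replicates 1 and 2, and 288 without TT control replicate 4. NIATv7_g09022 went from -0.34 ± 0.42 to -4.02 ± 0.91 in ET leaves under drought, but from -0.40 to 0.58 in EE and from -0.37 to 1.97 in TT, with an interaction of -4.66 ± 0.58 against EE (adjusted p 0.00036) and 6.03 ± 0.58 for TT against ET (adjusted p 8.6e-06). NIATv7_g34447 rose in EE leaves by 4.18 ± 0.58 (adjusted p 2.3e-06) and not detectably in ET (0.21, adjusted p 0.764) or TT (-0.82, adjusted p 0.217). Its interactions were -3.97 ± 0.83 for ET (adjusted p 0.0153) and -5.01 ± 0.83 for TT (adjusted p 0.00092). NIATv7_g37923 went from -1.50 to 2.85 in EE leaves and from -1.45 to -2.04 in TT leaves, an interaction of -4.94 ± 0.85. NIATv7_g17973 (4.0 ± 0.63) and NIATv7_g03207 (4.31 ± 0.21) responded more upward in TT than in EE, and NIATv1_g53851 (3.35 ± 0.66) and NIATv7_g06120 (3.22 ± 0.62) did so in ET. For TT against ET the other named genes were NIATv7_g03207 (4.41 ± 0.21), NIATv7_g38636 (-1.81 ± 0.34) and NIATv7_g08362 (-1.93 ± 0.48, adjusted p 0.0465), the last of which 13 of 16 fits that each left out 1 array did not call.

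NIATv7_g19342 was singled out after its values were seen, since it was also among the genes lower in ET leaves. It went from 2.56 ± 0.31 to 3.14 ± 0.34 in EE leaves under drought (mean ± SD, n = 4), from 1.36 ± 0.33 to -1.13 ± 0.21 in ET leaves and from 1.75 ± 0.32 to -1.42 ± 0.43 in TT leaves. The response differed from EE by -3.08 ± 0.32 in ET (adjusted p 9.9e-05) and -3.75 ± 0.32 in TT (adjusted p 1.5e-06), and not detectably between ET and TT (-0.68, adjusted p 0.358). In roots it fell in every genotype, with log2 changes of -5.33, -6.56 and -7.24 in EE, ET and TT. Slide as a block gave 940, 2036 and 1061 leaf interaction calls, with 499, 1325 and 446 of the unblocked calls among them. Replicates 3 and 4 alone with slide as a block gave 0, 36 and 3 in limma, with 3792 probes at an unadjusted p under 0.05 for ET and EE. The replicate pairs correlated at 0.253, 0.515 and 0.406. The interactions of ET and TT against EE correlated at 0.601, against 0.499 from sharing the EE arrays and 0.286 to 0.453 with those arrays split.

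**Figure D5:**
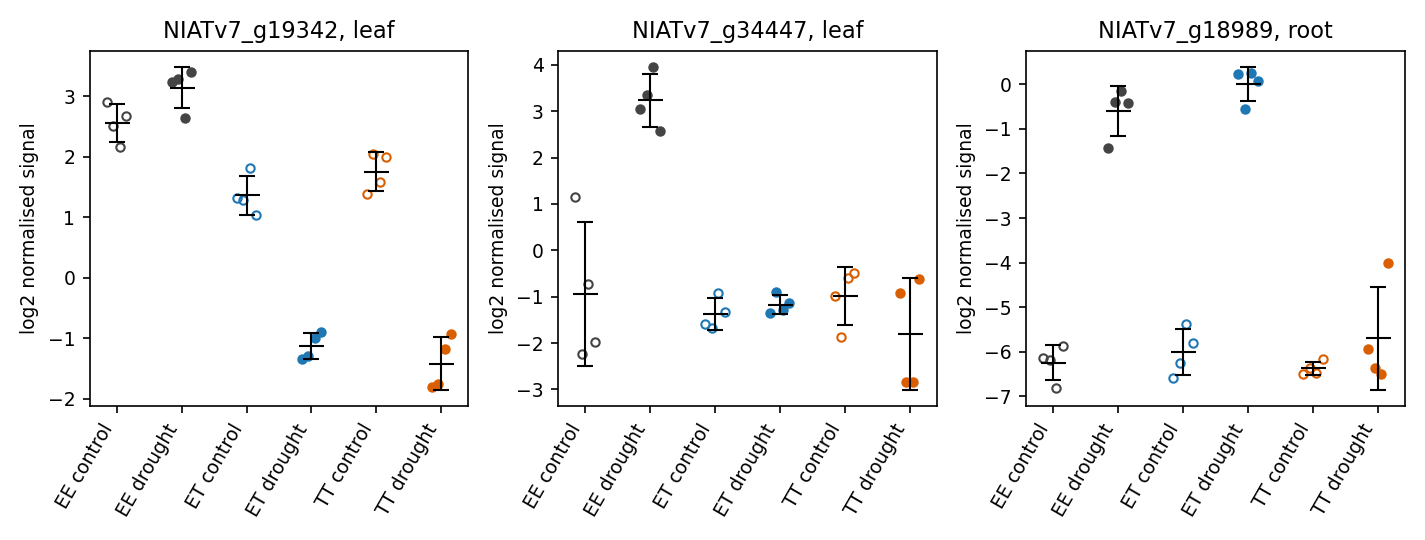
Log2 normalised signal (vertical axes) of NIATv7_g19342 and NIATv7_g34447 in leaves and NIATv7_g18989 in roots, with 1 point per array, open for control and filled for drought, and bars for mean ± SD of 4 arrays. In leaves under drought NIATv7_g19342 stands at 3.14 in EE, -1.13 in ET and -1.42 in TT.

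Root responses differed from EE at 521 probes in ET (202 up, 319 down) and at 2305 in TT (1058 and 1247). Leaving out 1 array gave 1567 to 3155 calls for TT and 174 to 604 for ET. The ET count was 250, 230 and 309 without EE control replicates 2, 3 and 4, 297 without EE drought replicate 4, 301, 333 and 261 without ET control replicates 1, 2 and 3, and 174, 331 and 345 without ET drought replicates 1, 2 and 4. NIATv7_g01571 rose more in ET (interaction 3.03 ± 0.75, adjusted p 0.0457) and TT (3.67 ± 0.75, adjusted p 0.0050) than in EE, and 13 of 16 fits that each left out 1 array did not call the ET difference. NIATv7_g42738 also responded more upward in ET (3.04 ± 0.66, adjusted p 0.0259, and 0.0506 to 0.0524 in 3 of 16 fits that did not call it, without EE control replicate 3, ET control replicate 2 or ET drought replicate 1), and NIATv7_g00344 did so in TT (5.21 ± 1.13). NIATv7_g32756 (-3.70 ± 0.62) and NIATv7_g33495 (-3.84 ± 0.70) responded more downward in ET, and NIATv7_g37802 (-4.59 ± 0.75) and NIATv7_g09977 (-4.43 ± 0.89) in TT. Slide as a block gave 846 calls for ET and 3711 for TT, including 410 and 2219 of the unblocked ones, and replicates 3 and 4 alone with that block, on 4 residual degrees of freedom, gave 0 and 1 in limma, with 2573 probes at an unadjusted p under 0.05 for ET. Of the probes called in replicates 1 and 2, 24 of 28 for ET and 1655 of 1793 for TT kept their sign there. Over all probes it was 62.4% and 65.6%. The replicate pairs correlated at 0.429 and 0.454. Called in both and in the same direction were 432 probes, with a correlation of 0.765 across all probes, against 0.498 from sharing the EE arrays and 0.196 to 0.504 with those arrays split.

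Most root interaction calls were larger changes in the direction that the remaining genotype also took. Of the 2118 calls for TT against EE that were called in ET as well, 1992 (94.1%) moved further in TT than in EE, against 75.2% of all probes called in ET. For ET against EE, judged by the direction in TT, it was 450 of 467 (96.4%), against 75.7% of all. In leaves it was 748 of 1096 (68.2%, against 55.95%) for TT against EE. For ET against EE in leaves it was 258 of 436 (59.2%, against 58.1%), near the share of all probes. Response size over all tested root probes was 0.884 ± 0.022 in EE, 1.01 ± 0.011 in ET and 1.04 ± 0.021 in TT (± SE, 4 arrays per regime). ET exceeded EE by 0.121 (exact permutation p 0.0262, 0.157 after adjustment over 6 comparisons) and TT exceeded EE by 0.153 (exact permutation p 0.0710, 0.213 adjusted), so neither passed the threshold after adjustment. In leaves the sizes were 0.947 ± 0.042, 0.984 ± 0.025 and 1.02 ± 0.016, with adjusted exact permutation p values of 0.355 to 0.509.

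TT and ET roots, which differ only in the scion, had 4 probes with different drought responses by limma, 0 up and 4 down in TT, against 1985 at an unadjusted p under 0.05. They belong to 2 genes, and since so few were called both were named after their values were seen. NIATv7_g18989 has 3 of the probes (adjusted p 2.4e-08, 0.00012 and 8.9e-06), all well above background on 0 control root arrays of any genotype, so the size of its responses has only lower bounds. On its brightest probe drought roots read -0.60 ± 0.57 in EE and 0.0042 ± 0.39 in ET, at least 17.8-fold and at least 22.2-fold above their controls. TT drought roots had this probe well above background on 1 of 4 arrays. On the probe that no TT drought root array had above background, EE drought roots were at least 9.38-fold and ET drought roots at least 15.8-fold higher. The fourth probe, of NIATv7_g39132, changed by -1.0 in TT and -0.27 in ET roots, an interaction of -0.73 ± 0.12 (adjusted p 0.0476) that 14 of 16 fits with 1 array left out did not call. The other tested probe of NIATv7_g39132 was not called, and went from 6.50 to 5.51 in TT and from 6.52 to 6.24 in ET roots. With slide as a block the contrast had 6 calls, the 4 probes called without it among them.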

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

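Apart from the regroupings of arrays, the position of root ET control replicate 3 over 4312 probes and the response size after quantile normalisation, the tests in this part were chosen only after the result was seen. An array lay far from the other 3 of its group in 13 of 206 groups tested, and chance gives about 1 in 20.

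Root ET control replicate 3 had a line marker index of 0.947, NIATv7_g03207 at 7.38 against a mean of -1.44 in the other 3 arrays, and NIATv7_g34157 at 2.89 against -0.91. A swap with an EE root array cannot be judged from the index. The lowest index of the EE root arrays was 0.912, but the marker rule itself required every EE array to read above the TT arrays. Against a poor array speaks the mean correlation of 0.975 of root ET control replicate 3 with its own group, where the lowest of the other root arrays was 0.959. RNA from EV roots would place it near EE over the 4312 other probes called between TT and EE roots, but its position was 0.415, beside 0.235 to 0.337 in the other ET controls, 0.645 to 1.13 in EE controls and 0.416 in root ET drought replicate 3 on the same slide. Over 427 probes called with slide as a block root ET control replicate 3 lay at 0.609, again below every EE control (0.827 to 1.03). Both sets were chosen with the EE and TT arrays themselves, which draws those arrays toward their own ends of the scale. An EV root array that took no part may fall short of them, so neither set decides on RNA from EV roots alone. That part of the RNA came from EV roots stays open as well, since 0.609 lies above the other ET controls (0.185 to 0.448) by less than their own range. A local loss of silencing, which may give the same readings, was not tested.

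ET and EE leaves differed at 4598 probes, and slide 3, which holds ET replicates 1 and 2, is a candidate source of many of these calls. Leaf ET replicates 1 and 2 were set against replicates 3 and 4, and control roots on slide 3 against other control roots. Both differences correlated across probes at 0.588. With EE and TT leaves, none of whose arrays lie on slide 3, the correlations were -0.414 and -0.612. Correlations of this size thus arise without slide 3 among the leaf arrays, so the 0.588 does not single out slide 3. Graft genotype as the whole cause was examined with the top 500 probes of replicates 1 and 2. Their median effect of 1.62 was 0.15 in replicates 3 and 4, a share of 0.0901, while for TT and EE leaves it went from 1.25 to 1.06. Such shrinkage is not particular to slide 3, since in roots it went from 1.02 to 0.07 for TT and ET, 0.98 to 0.43 for TT and EE and 0.85 to 0.35 for ET and EE. The probes were also chosen for large effects in replicates 1 and 2, which alone brings shrinkage, so this test cannot decide. With slide as a block the median difference of the 4598 went from 0.47 (median standard error 0.120) to 0.35 (0.151), so calls ended through both a smaller difference and a wider error, and 556 remained among 623. A biological part due to the rootstock stays open, since replicates 1 and 2 of each genotype share a slide.

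The root drought response of TT differed from that of EE at 2305 probes and that of ET at 521, mostly toward a smaller response in EE. A single EE root array as the whole cause is argued against, for TT, by the lowest number of TT and EE calls without an EE array, 1581. For ET the calls fell to 230 without EE control replicate 3, 250 without EE control replicate 2 and 174 without ET drought replicate 1. The median difference of the 521 calls kept a share of 0.954 or more of its size without each EE array in turn. That share was 0.951 even without ET drought replicate 1. Probes are called only where arrays agree, so this share could hardly fall, and for ET the question stays open. With slide as a block 2219 of 2305 and 410 of 521 calls remained, and the median ET difference was 1.01 times its unblocked size. This cannot decide on slide, since control and drought arrays of replicates 1 and 2 of a genotype share a slide. A constant slide effect then largely cancels, and one that differs between regimes stays despite the block. In replicates 3 and 4 alone with that block, 4 residual degrees of freedom left 1 TT call. There 92.3% of the 1793 TT probes called in replicates 1 and 2 kept their sign, against 65.6% of all probes. For TT and EE these arrays lie on other slides, which argues against slide as the whole cause, while for ET it stays open. A compressed signal range is argued against by the response size of EE relative to the mean of ET and TT, which was 0.866 with percentile scaling and 0.862 after quantile normalisation, which gives every array the same range, although the response sizes themselves did not pass the threshold (adjusted exact permutation p 0.157 for ET and 0.213 for TT). That a silenced rootstock may strengthen the root response remains a hypothesis, and differences in plant growth or in the speed of soil drying were not measured here.

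The other single arrays far from their group had these values, with the mean of the other 3 in brackets where it was taken. The line marker index was 1.03 in leaf EE control replicate 1 and -0.0955 in root TT control replicate 2. In leaves, NIATv7_g06269 was -0.53 in EE control replicate 1 (-2.66), NIATv7_g01571 was 6.58 in ET drought replicate 4 (5.96), NIATv7_g04799 was 3.1 in TT control replicate 1 (2.29) and NIATv7_g08362 was 4.71 in TT drought replicate 4 (3.50). In roots, NIATv7_g30051 was -4.24 in EE drought replicate 2 (-3.16), NIATv7_g03207 was 4.81 in ET drought replicate 2 (1.60), NIATv7_g01571 was -0.79 in EE control replicate 4 (1.89) and NIATv7_g37802 was -5.49 in TT drought replicate 1 (-2.34).

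Differences between drought responses passed their test at the following values on the log2 scale. In leaves ET differed from EE by 3.35 (NIATv1_g53851), 3.22 (NIATv7_g06120), -3.97 (NIATv7_g34447) and -4.66 (NIATv7_g09022). TT differed from EE by 4.31 (NIATv7_g03207), 4.0 (NIATv7_g17973), -4.94 (NIATv7_g37923) and -5.01 (NIATv7_g34447), and from ET by 6.03 (NIATv7_g09022), 4.41 (NIATv7_g03207), -1.81 (NIATv7_g38636) and -1.93 (NIATv7_g08362). In roots ET differed from EE by 3.04 (NIATv7_g42738), 3.03 (NIATv7_g01571), -3.70 (NIATv7_g32756) and -3.84 (NIATv7_g33495), and TT from EE by 5.21 (NIATv7_g00344), 3.67 (NIATv7_g01571), -4.43 (NIATv7_g09977) and -4.59 (NIATv7_g37802).

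Each count was set against other splits of the same arrays, 35 for a drought contrast and 100 for the others. For drought, chance can be excluded in leaves (real count, then highest other: 20320 and 59 in EE, 21147 and 947 in ET, 20873 and 11 in TT) and in roots (18461 and 1580, 21069 and 5, 21514 and 8). It can also be excluded for genotype differences in leaves (ET and EE 4598 and 301, TT and EE 5362 and 1373, TT and ET 7583 and 3686) and in roots (967 and 296, 4319 and 2584, 398 and 73). Since slide goes with genotype in replicates 1 and 2, these genotype counts do not separate genotype from slide, and blocking by slide gave 623, 3348 and 2159 in leaves and 29, 432 and 5 in roots. The fall in counts does not itself name slide as the source, since with the block the median difference of the unblocked calls went from 0.55 to 0.54 in TT and EE leaves and, in roots, from 0.66 to 0.62, 0.51 to 0.44 and 0.63 to 0.58, while median standard errors rose. In leaves it went from 0.47 to 0.35 for ET and EE and from 0.52 to 0.35 for TT and ET. Splits that part replicates 1 and 2 from 3 and 4 gave at most 644 calls, in TT and EE leaves, fewer than the real count in each contrast.

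For interactions the splits shuffled genotype within each regime, which also broke up the average genotype differences and put them into the residual spread. This may lower the counts of the other splits, so they cannot exclude chance for the interaction alone. For ET and EE only the real split reached the real count, in leaves (556, highest other 333) and roots (521 and 325). The same held for TT and EE in roots (2305 and 2075). For TT and EE in leaves 2 of 100 splits gave as many as the real 1382, and the highest other gave 1821. Slide explains 0.521 of that split's coding against 0.0417 of the real coding, and blocking by slide gave 2036 real calls. For TT and ET in leaves chance cannot be excluded, because 5 of 100 splits gave as many as the real 454. The highest gave 3430, which is 755.5% of the real count and points to a structure of the samples. Slide explains 0.542 of that split's coding and 0.0417 of the real coding, and blocking by slide gave 1061 calls. For TT and ET in roots 3 of 100 splits gave as many as the real 4 calls, and the highest other gave 5. Of the 4 probes, 3 belong to the same gene, NIATv7_g18989, so this count is too small to exclude chance.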

How the results depend on the processing

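Of these settings, percentile scaling over detected probes, a fitted spike-in curve and scan day as blocks, leaving out slide 3 or the 2 doubted ET root arrays, replicates 1 and 2 for genotype contrasts and interactions, and replicates 3 and 4 for drought were tests chosen after the data were seen. Of 293 counts under alternatives, 222 stayed within 1.5 times the reported count and 71 did not. For named genes, 1058 of 1138 values kept direction and side of the threshold, 77 kept direction without passing it, 2 values without a test moved and 1 reversed. Most of the 77 arose with replicates 3 and 4 and a slide block (34), replicates 1 and 2 (14) and slide as a fixed block (9). The reversed value is the median of root-biased probes in EE leaves, 0.59 as reported and -0.17 with normexp. Unless said otherwise, the cause was not tested.

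Drought counts left that range only where probes or arrays were changed: 30891 in EE and 31488 in TT leaves without the filter, with more probes tested, and 11660, 13773 and 13880 in EE, ET and TT roots with replicates 3 and 4, with fewer arrays. Normexp moved the median drought change of all leaf probes by -0.145, -0.104 and -0.162 in EE, ET and TT, and scaling over detected probes by 0.145, 0.180 and 0.125. Accordingly 7807 probes rose and 12462 fell in EE leaves with normexp, and 11600 and 9084 with scaling over detected probes, so the balance of risen and fallen leaf probes depends on the scaling. With normexp the median of all probes in EE leaves was -0.16, close to the -0.17 of the root-biased probes. Scaling over detected probes also gave 417 higher and 573 lower probes for root ET and EE, and 262 up and 190 down for the leaf TT and ET interaction.

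Without the filter, ET and EE differed at 2538 probes in leaves and 573 in roots and TT and ET roots at 241, leaf interactions numbered 221, 776 and 201 (ET and EE, TT and EE, TT and ET), and the root ET and EE interaction 229. Requiring signal on every array left 0 root TT and ET interaction calls in limma (1646 at an unadjusted p under 0.05), and removed the 3 probes of NIATv7_g18989, which are at background in control roots. The authors' values gave 880 leaf ET and EE interactions. Only the groups of a contrast gave 344 for that interaction and 299 for leaf TT and ET, with fewer arrays to estimate variance.

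With slide as a fixed block, leaf calls were 623, 3348 and 2159 for ET and EE, TT and EE, and TT and ET, with interactions of 940 (ET and EE) and 1061 (TT and ET). Root calls were 29, 432 and 5, with interactions of 846 and 3711 against EE. As a random block slide gave 2327 (ET and EE) and 4468 (TT and ET) in leaves with interactions of 1012, 2187 and 920, and 453, 2758 and 180 in roots with interactions of 1072, 3700 and 10. Scan day as a block gave 3043 and 4489 for leaf ET and EE and TT and ET, and ET and EE interactions of 932 in leaves and 813 in roots. Without slide 3 there were 654 leaf ET and EE calls and 2493 leaf TT and ET calls, with interactions of 180 and 116, and 224 root ET and EE interactions. Genotype counts thus fell with a slide block while interaction counts against EE rose.

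Replicates 1 and 2 alone gave 8289 and 3397 leaf calls for ET and TT against EE, interactions of 68 and 447, 28 root ET and EE interactions, 1245 root TT and ET calls and 2 interactions. Replicates 3 and 4 with a slide block gave 238, 1806 and 1168 leaf calls (ET and EE, TT and EE, TT and ET) with interactions of 0, 36 and 3, and 3, 47 and 0 root calls with interactions of 0, 1 and 0, with 4 residual degrees of freedom. Where limma gave 0 calls there, probes at an unadjusted p under 0.05 numbered 3792 for the leaf ET and EE interaction and, in roots, 2573 for that interaction, 1752 for TT and ET and 1923 for their interaction. Without the 2 doubted ET root arrays, root TT and ET calls were 255 and root ET and EE interactions 197.

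Nothing in the labels pairs arrays by replicate number, and with their group means removed 27 of 60 leaf and 31 of 60 root pairs with the same number correlated above 0.1 (median 0.0631 and 0.110), against 51 and 47 of 180 pairs with different numbers (median -0.014 and -0.0322). With the replicate number as a block, root ET and EE calls were 1529, root TT and ET calls 692, and their interactions 789 and 10.

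Leaving out 1 array at a time, 209 of 240 counts stayed within 1.5 times. Drought calls ranged over 19063 to 19798, 20151 to 20597 and 19880 to 20226 in EE, ET and TT leaves and 16815 to 18120, 19689 to 20576 and 20334 to 21130 in roots. TT and EE calls ranged over 4498 to 5140 in leaves and 3190 to 5069 in roots, with root interactions of 1567 to 3155 and leaf interactions of 916 to 1627, lowest without TT drought replicate 2. Leaf ET and EE calls (2753 to 6086) fell without ET control replicate 1 (2753), ET drought replicate 1 (2996) or ET control replicate 2 (3056), and their interactions (318 to 627) without ET control replicate 3 (318) or EE drought replicate 4 (338). Leaf TT and ET calls were 5576 to 8663, and their interactions (246 to 599) fell without TT drought replicates 1 (285) or 2 (246), ET control replicates 1 (302) or 2 (294), or TT control replicate 4 (288). Root ET and EE calls (523 to 1183) fell without EE control replicate 2 (532), ET drought replicate 1 (523) or ET control replicate 2 (579).

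Root ET and EE interactions ranged over 174 to 604 and fell without EE control replicates 2 (250), 3 (230) or 4 (309), EE drought replicate 4 (297), ET control replicates 1 (301), 2 (333) or 3 (261), or ET drought replicates 1 (174), 2 (331) or 4 (345). Root TT and ET calls (203 to 825) fell without TT drought replicates 1 (203) or 2 (203), TT control replicate 3 (248), ET control replicates 1 (258) or 2 (249), or ET drought replicate 3 (230), and rose without TT drought replicate 4 (825). Their interactions were 3 to 6. Of the values of named genes, 901 of 944 kept their call. The 43 losses fell on 4 interactions, all without a change of direction. In roots NIATv7_g42738 (ET and EE) was not called without ET drought replicate 1 (adjusted p 0.0524, limma), ET control replicate 2 (0.0511) or EE control replicate 3 (0.0506). NIATv7_g01571 (ET and EE) was called only without EE control replicate 4, ET control replicate 2 or ET drought replicate 3, with adjusted p up to 0.104 otherwise. NIATv7_g39132 (TT and ET) was called only without TT control replicate 4 or TT drought replicate 4 (up to 0.128 otherwise), and leaf NIATv7_g08362 (TT and ET) only without ET drought replicate 4, ET control replicate 3 or TT drought replicate 4 (up to 0.114).

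Signal over background limits what can be read: dim probes such as NIATv7_g18989 in control roots have only lower bounds for their folds. The mean over all probes of a gene and the estimated correlation between genes were not run, since both concern gene lists, which need gene names.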
